A study of Mus musculus and Anolis carolinensis with 21 samples.

How the data were processed

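H3K27ac ChIP-seq was run on 9 mouse libraries (strain ICR) and 3 green anole lizard libraries, and 9 input libraries of sheared chromatin were prepared beside them. Crosslinked tissue was sonicated, chromatin was pulled down with an antibody against H3K27ac, and 50-bp single-end reads were taken on an Illumina HiSeq instrument. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.1.0, MACS2 2.0.10.20130501 and bedtools (no version), without the role or settings of each, and the mouse build mm9. The notes do not name the lizard build, and lizard positions are those of the deposited lists.

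Each library came as a deposited list of peaks with chromosome, start, end, name and score. The score is a whole number that the authors' peak caller gave each peak; its scale is stated nowhere, so it served only to rank peaks within a library and to choose named regions. The lowest score was 13 in every list. Peaks within a list did not overlap and lay at least 51 bp apart. No list of the 9 input libraries was used here. Sequencing depth was not given in the sources used here, so the peaks per library and the bases they cover stand in for it. Covered bases were 7.12 and 19.1 Mb in forelimb, 6.96 and 18.1 Mb in hindlimb, 14.2 and 16.3 Mb in genital tubercle, 13.7 and 9.21 Mb in eye and 7.07 Mb in flank, and in the lizard 20.2 Mb in forelimb, 24.5 Mb in hindlimb and 8.98 Mb in hemiphallus. The number of peaks limits the precision of every share, and intervals for shares are exact Clopper-Pearson 95% intervals, which cover counting error only. How calls would change with depth could not be computed.

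Overlapping peaks of all lists of a species were merged into regions, and a region counted as called in a library when at least 1 bp of a peak of that library lay in it. Positions are counted from 1 and include both ends. The median region was 281 bp long in the mouse and 319 bp in the lizard. A class of regions was defined by the libraries that call it: every library of the tissues in the class and no library of the tissues against which it was set. Overlap between lists was the share of peaks with at least 1 bp in the other list, and the Jaccard index of covered bases. Chance overlap was the mean over 20 random shifts of the peaks along their chromosomes. Means are given with the SD over pairs of libraries or over the 2 libraries of a tissue. Pairs share libraries and are not independent.

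Libraries were grouped by the tissue in their labels. Replicates were compared by an exact one-sided permutation test of the Jaccard index within against between tissues, over all pairings of the 8 libraries of replicated tissues. Forelimb was set against hindlimb, limbs against genital tubercle, and limbs with genital tubercle against eye and flank, each beside the other splits of the same libraries. Lizard tissues were compared without a test. Comparisons, the named-region rule and most alternatives were chosen before the data were examined. The counts over splits of the 9 libraries were read against chance only after the results were seen. No gene was to be named without an annotation of the genome build, and none was used here. In that case the rule takes, for each class, the 5 regions with the highest score of their weakest called library and the 3 windows of 1 Mb with most regions of the class. Scores of different libraries enter that ranking unscaled. Named regions close together on a chromosome were described as a stretch, with the bases covered by each tissue.

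The alternatives were lists of equal size (19621 top-scoring peaks per mouse library and 23906 per lizard library), the top-scoring 50% of each list, an overlap of at least 50% of the shorter interval, peaks within 500 bp merged, bins of 500 bp, a call in at least 1 replicate per tissue, pairs of libraries with the same number only, and leaving out each mouse library in turn. Peaks resized to 1000 bp around their midpoint, equal lists of such peaks, and leaving out forelimb 1 together with hindlimb 1 were added after the short peaks of those libraries were seen. The 16 gene lists fixed in advance and the restriction to regions far from transcription starts need an annotation and were not run. Counting was tested on 22500 simulated sites with a detection probability of 0.9 per library, where the 8 simulated classes were recovered at 0.961 to 1.02 times the expected number. That number already allows for missed calls, so the ratio tests the counting and not how fully real classes are recovered. Simulated sites lay well apart and were detected equally in all libraries, unlike the deposited lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.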

Results

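H3K27ac, a histone mark found at active enhancers and promoters, was profiled by ChIP-seq in the developing limbs and external genitalia of the mouse and of the green anole lizard (Anolis carolinensis). The mouse set held 9 libraries from ICR embryos. Forelimb and hindlimb at E11.5 (days of embryonic development), genital tubercle (the bud of the external genitalia) at E12.5 and eye at E10.5 had 2 libraries each, and flank mesenchyme at E11.5 had 1. The lizard set held 1 library each of forelimb and hindlimb at stages 7 to 8 and of the hemiphallus, the genital bud of lizards, at stages 9 to 11, each from pooled tissue and without replicates. Limb and genital samples differed in stage in both species, so tissue and stage could not be separated.

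The forelimb lists held 40303 and 45170 peaks, the hindlimb lists 35166 and 44951, the genital tubercle lists 34531 and 38867, the eye lists 34382 and 22947, and the flank list 19621. The lizard lists held 47573 peaks in forelimb, 53464 in hindlimb and 23906 in hemiphallus. Peaks of mouse forelimb 1 and hindlimb 1 were short, with medians of 122 and 137 bp against 265 to 296 bp in the other 7 mouse lists. Their shortest peaks were 64 and 70 bp, against 130 to 150 bp in those 7 lists. Merging overlapping peaks gave 90434 regions in the mouse and 67114 in the lizard. Of the mouse regions, 42146 (46.6%) were called in 1 library and 5851 (6.47%) in all 9. Sequencing depth was not given in the sources used here, so each call was conditional on a depth that is unknown. Nothing in the labels says that replicates came from separate animals, so differences between replicates may be technical. The p-values below rank the pairing by tissue among all pairings of these libraries and cover these samples only.

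By the Jaccard index, the covered bases a pair of lists share divided by those covered by either, genital tubercle and eye libraries resembled their own replicate most, and limb libraries did not. The index was 0.584 between the genital tubercle libraries and 0.469 between the eye libraries. Forelimb 1 shared more with hindlimb 1 (0.403) than with forelimb 2 (0.313). Likewise forelimb 2 and hindlimb 2 reached 0.531, against 0.331 between the hindlimb libraries. By the share of peaks overlapped, forelimb 1 and hindlimb 1 did match their own replicate most (82.97% of forelimb 1 peaks in forelimb 2 against 74.0% in hindlimb 2, and 86.7% of hindlimb 1 peaks in hindlimb 2 against 83.8% in forelimb 2), while forelimb 2 and hindlimb 2 matched each other most (68.8% and 71.5%). The mean Jaccard index within a tissue was 0.424 ± 0.127 (SD, n = 4 pairs) and between tissues 0.30 ± 0.0698 (SD, n = 24 pairs), a difference of 0.124. An exact one-sided permutation test over all ways to pair the 8 libraries gave p = 0.019, where the smallest possible was 0.00952, and pairing the limb libraries by number in place of limb gave a larger difference of 0.209. The exact one-sided p rose to 0.0667 without eye 1, 0.0762 without eye 2, 0.114 without genital tubercle 1 and 0.105 without genital tubercle 2, with differences of 0.100, 0.0987, 0.0729 and 0.0692.

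**Figure D1:**
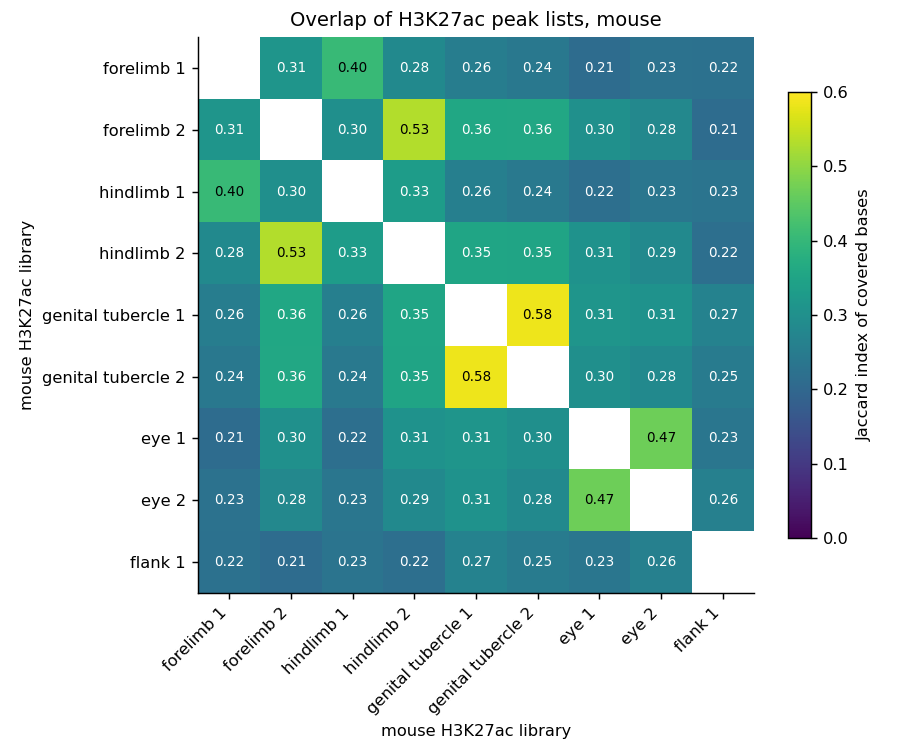
Jaccard index of covered bases (colour scale from 0 to 0.6, no unit) for each pair of the 9 mouse H3K27ac libraries, listed by tissue and replicate on both axes. The genital tubercle pair stood at 0.58 and the eye pair at 0.47, while forelimb 2 and hindlimb 2 (0.53) exceeded the forelimb pair (0.31) and the hindlimb pair (0.33).

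Forelimb and hindlimb at E11.5 were compared to find regions active in 1 limb and not the other. The forelimb calls with the highest scores lay together on mouse chromosome 5, where 4 of the 5 named regions fell in a 47.7-kb stretch from 120246347 to 120294056. Forelimb peaks covered 26.4 ± 4.29 kb of it (SD, n = 2) and hindlimb peaks 0 kb. The hindlimb counterpart was a 14.6-kb stretch of chromosome 13 from 55924931 to 55939572, covered over 13.9 ± 0.892 kb in hindlimb (SD, n = 2) and 0 kb in forelimb. A second hindlimb stretch, on chromosome 15 from 102790541 to 102796943, was covered over 5.87 ± 0.465 kb in hindlimb (SD, n = 2) and 0 kb in forelimb.

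None of these 3 stretches was confined to 1 limb among the tissues sampled. In the genital tubercle, peaks covered 17.6 ± 0.991 kb of the chromosome 5 stretch, 10.6 ± 0.0912 kb of the chromosome 13 stretch and 6.09 ± 0.0361 kb of the chromosome 15 stretch (SD, n = 2 each). Flank peaks covered 5.18 kb on chromosome 13, 0.24 kb on chromosome 15 and 0 kb on chromosome 5, and eye peaks 0 kb of all 3. The remaining named forelimb region, a 242-bp region on chromosome 7 from 19576119 to 19576360, was called in forelimb alone. The remaining hindlimb region, on chromosome 13 from 56062306 to 56064733, was covered over 2.38 ± 0.0170 kb in hindlimb and 1.26 ± 0.117 kb in genital tubercle (SD, n = 2 each).

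Windows with most regions of each kind repeated 2 of these places. The window from 120 to 121 Mb on chromosome 5 held 12 forelimb regions without a hindlimb call (9.6% of its regions), and the window from 102 to 103 Mb on chromosome 15 held 13 hindlimb regions without a forelimb call among 140 (9.29%). Across the genome these shares were 2.52% and 1.52%. The other forelimb windows were 110 to 111 Mb on chromosome 8 (14 of 195 regions) and 45 to 46 Mb on chromosome 11 (11 of 101). On the hindlimb side, adjoining windows on chromosome 10 from 119 to 120 Mb and from 120 to 121 Mb held 9 of 116 and 12 of 198.

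Most regions called in both libraries of 1 limb were called in both libraries of the other (69.8% for forelimb, 74.4% for hindlimb). All 4 limb libraries called 14329 regions, against 2283 called in both forelimb libraries and no hindlimb library and 1372 in the reverse. The 5 common regions with the highest scores, on chromosomes 2, 3, 15, 5 and 1, were called in all 9 mouse libraries. The 4 limb libraries can be split in 3 ways, so no share under 1 in 3 was possible, and the split by limb parted fewer regions (3655) than the split by library number (6507, of which 6169 were in both libraries numbered 2). Forelimb regions without a hindlimb call numbered 11540 without forelimb 1, 7602 without forelimb 2 and 5626 without hindlimb 2; hindlimb regions without a forelimb call numbered 10639 without hindlimb 1, 3914 without hindlimb 2 and 4785 without forelimb 2, and they outnumbered the forelimb kind (3004) once hindlimb 1 was left out. With equal lists the forelimb and hindlimb kinds were close, at 1019 and 970.

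**Figure D2:**
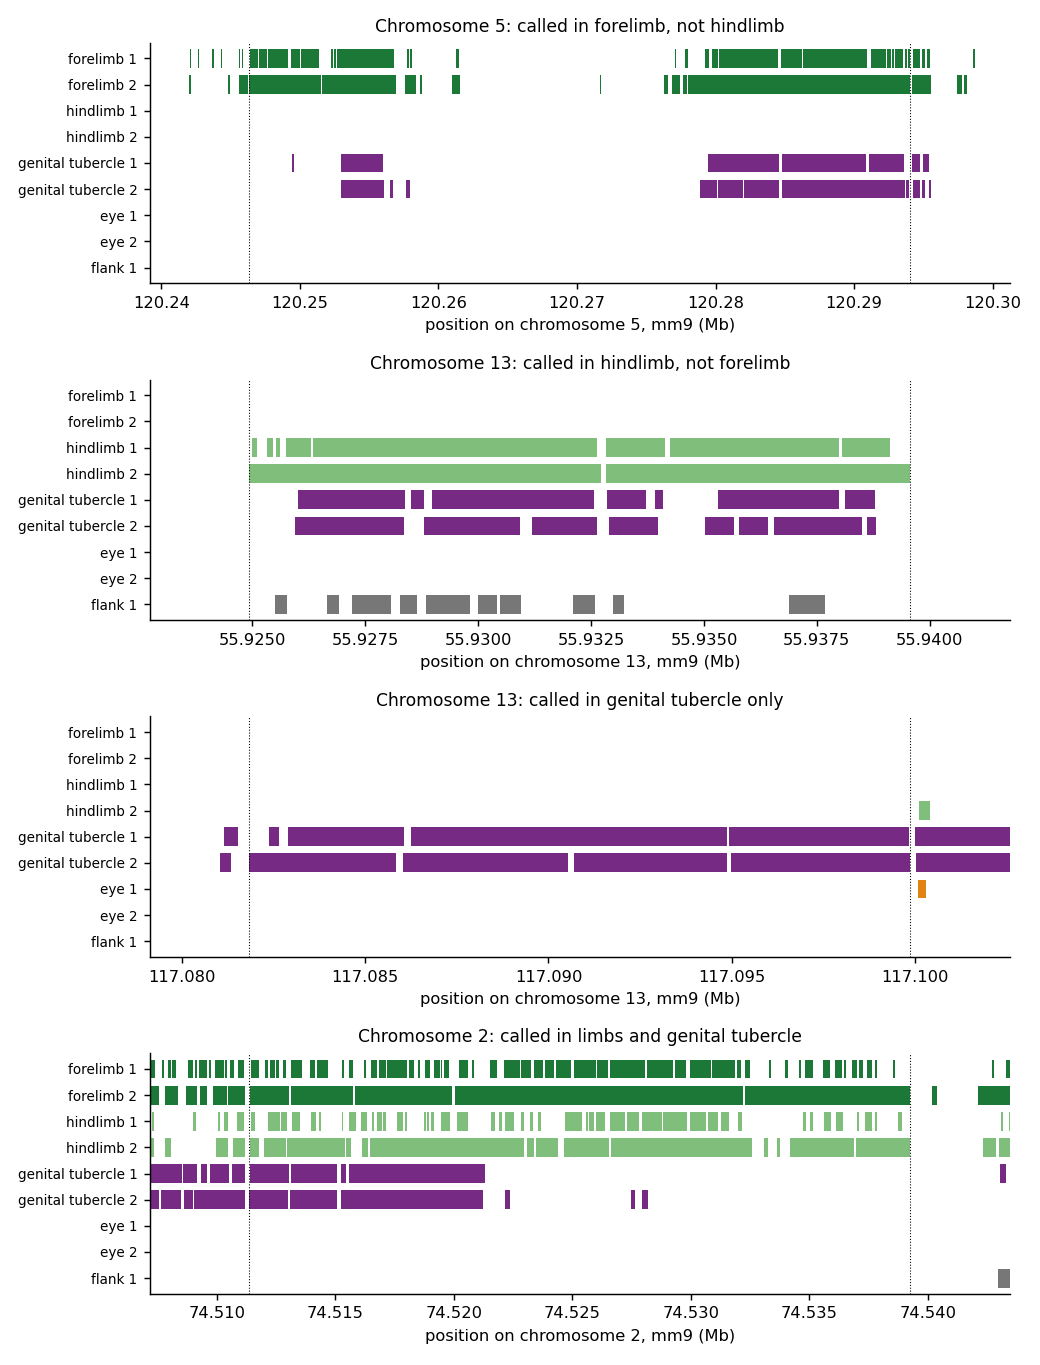
Deposited peaks (bars, 1 line per mouse library) against position in Mb (mm9) in 4 named stretches, whose ends are dotted. Hindlimb peaks covered 0 kb of the chromosome 5 stretch and forelimb peaks 0 kb of the chromosome 13 stretch from 55924931, while genital tubercle peaks lay in all 4 stretches, alone in the one from 117081841 to 117099872, just past which hindlimb 2 and eye 1 each had a peak.

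Limbs and genital tubercle, the outgrowths that the title of the series sets side by side, were compared with eye and flank beside them. Of the 14329 regions in all 4 limb libraries, 73.0% (95% exact Clopper-Pearson interval 72.3 to 73.7%, counting error only) were also called in both genital tubercle libraries and 19.6% in neither. Both eye libraries called 57.6% of the same regions and the flank library 50.2%, and with equal lists the shares were 77.9% in genital tubercle, 69.3% in eye and 66.3% in flank. Limb regions without a genital tubercle call were led by a 9853-bp region on chromosome 3 from 99057275 to 99067127. Forelimb peaks covered 8.14 ± 2.04 kb of it, hindlimb peaks 8.67 ± 1.17 kb (SD, n = 2 each) and those of the other tissues 0 kb. Next came regions on chromosome 1 from 164761700 to 164762492, chromosome 13 from 60367837 to 60369034, chromosome 3 from 86345668 to 86349623 and chromosome 10 from 44860832 to 44862606, of which those on chromosome 1 and on chromosome 3 were called in both eye libraries too.

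The window with most limb regions of this kind, from 52 to 53 Mb on chromosome 6, held 26 of the 2809 among its 203 regions (12.8%), but genital tubercle peaks also covered 69.3 ± 4.82 kb of it, beside 82.9 ± 35.6 kb in forelimb and 94.2 ± 37.0 kb in hindlimb (SD, n = 2 each). By contrast the window from 140 to 141 Mb on chromosome 1, with 19 of 81 regions (23.5%), was nearly empty outside the limbs. Peaks covered 22.1 ± 13.8 kb of it in forelimb, 22.3 ± 10.02 kb in hindlimb, 0.139 ± 0.196 kb in genital tubercle and 1.28 ± 0.426 kb in eye (SD, n = 2 each), and 0.395 kb in flank. The window from 33 to 34 Mb on chromosome 2 held 21 of 133 (15.8%).

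Genital tubercle regions without a limb call were led by a region on chromosome 13 from 99272073 to 99275064, called in both eye libraries as well. An 18.0-kb stretch of the same chromosome from 117081841 to 117099872 held peaks over 17.3 ± 0.430 kb in genital tubercle (SD, n = 2) and 0 kb in every other mouse library. Genital tubercle peaks went on past its end, where hindlimb 2 (117100116 to 117100409) and eye 1 (117100090 to 117100297) had peaks too. The other named regions lay on chromosome 17 from 12862205 to 12863296, also called in flank, and on chromosome 9 from 55387509 to 55388718. The adjoining windows on chromosome 5 from 119 to 120 Mb and from 120 to 121 Mb held 51 of 166 regions (30.7%) and 41 (32.8%). In the first of these windows peaks covered 47.9 ± 2.11 kb in genital tubercle, 3.88 ± 3.37 kb in forelimb, 3.42 ± 3.07 kb in hindlimb and 2.46 ± 1.28 kb in eye (SD, n = 2 each), and 18.4 kb in flank. The window from 120 to 121 Mb is the one that held the forelimb stretch, and peaks there covered 71.2 ± 3.59 kb in genital tubercle, 35.6 ± 11.4 kb in forelimb and 5.02 ± 5.50 kb in hindlimb (SD, n = 2 each).

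Across the genome, 10461 regions were called in all 6 limb and genital tubercle libraries, 2809 in the 4 limb libraries alone of these and 5629 in genital tubercle alone of these. The split into limbs and genital tubercle parted 8438 regions, the most of the 15 splits of these libraries into 4 and 2, and the next highest parted 3582. The other 2 splits that kept each tissue whole parted 1793 and 1390. Each of the 4 limb libraries had a higher mean Jaccard index with genital tubercle than with eye or flank. The means were 0.302 ± 0.0569 with genital tubercle (SD, n = 8 pairs), 0.258 ± 0.0385 with eye (SD, n = 8 pairs) and 0.221 ± 0.00749 with flank (SD, n = 4 pairs). The difference between genital tubercle and eye was smaller than the spread between pairs, but that spread includes differences between limb libraries. With genital tubercle and with eye, the mean index was 0.248 and 0.220 in forelimb 1 and 0.358 and 0.290 in forelimb 2. It was 0.251 and 0.227 in hindlimb 1 and 0.352 and 0.296 in hindlimb 2. Seen from the genital tubercle, the order of limbs and eye turned on the limb library: the index was 0.351 to 0.3597 with forelimb 2 and hindlimb 2, 0.284 to 0.313 with eye, and 0.241 to 0.259 with forelimb 1 and hindlimb 1, whose peaks were short. Equal lists gave 0.387 to 0.397, 0.322 to 0.344 and 0.242 to 0.26 in that order. With 2 genital tubercle and 2 eye libraries an exact two-sided test cannot go below p = 0.333. Genital tubercle regions numbered 12809 without genital tubercle 1 and 10016 without genital tubercle 2, limb regions numbered 4365 without forelimb 1, and with forelimb 1 and hindlimb 1 both left out limb regions (9258) outnumbered genital tubercle regions (6051).

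Regions shared by limbs and genital tubercle and absent from eye and flank were counted next. A total of 1052 regions (1.16%) were called in all 6 limb and genital tubercle libraries and in none of the other 3. An 8121-bp region on chromosome 6 from 52192345 to 52200465 ranked first and was covered over 7.20 ± 1.07 kb in forelimb, 7.35 ± 1.07 kb in hindlimb and 7.27 ± 0.387 kb in genital tubercle (SD, n = 2 each). The second, on chromosome 11 from 8557086 to 8560591, was covered over 2.36 ± 1.04 kb, 2.82 ± 0.573 kb and 2.95 ± 0.123 kb in the same order. On chromosome 3 the region from 55298543 to 55303425 had 3.91 ± 1.07 kb, 3.86 ± 0.648 kb and 4.21 ± 0.0184 kb covered. The fourth lay on chromosome 10 from 25103670 to 25107477.

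The fifth, on chromosome 2 from 74511366 to 74539260, was 27895 bp long, the longest merged region in the mouse. Forelimb peaks covered 22.0 ± 7.75 kb of it, hindlimb peaks 18.8 ± 8.65 kb and genital tubercle peaks 9.88 ± 0.501 kb (SD, n = 2 each). Past 74521290 genital tubercle 1 had no further peak in it, and genital tubercle 2 had only small ones, with scores of 63, 28 and 44. Forelimb 2 peaks went on to 74539260. The region was joined by merging overlapping peaks, so its call in genital tubercle did not extend over its whole length. Its window, from 74 to 75 Mb, held the most shared regions, 17 of 148 (11.49%). In that window peaks covered 53.4 ± 23.8 kb in forelimb, 38.06 ± 20.002 kb in hindlimb, 54.8 ± 3.41 kb in genital tubercle and 0.779 ± 0.198 kb in eye (SD, n = 2 each), and 7.14 kb in flank. The windows from 29 to 30 Mb on chromosome 14 and from 55 to 56 Mb on chromosome 3 each held 14 of 167 (8.38%). No other of the 84 splits of the 9 libraries into 6 and 3 gave as many shared regions, and the next, which left out forelimb 1, hindlimb 1 and flank, gave 467. Most of these splits parted replicates, and the other 3 that kept each tissue whole gave 241, 50 and 28. The count rose to 1609 without eye 1, was 310 when every list was limited to its 19621 top-scoring peaks and 3832 when 1 replicate per tissue sufficed.

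**Figure D3:**
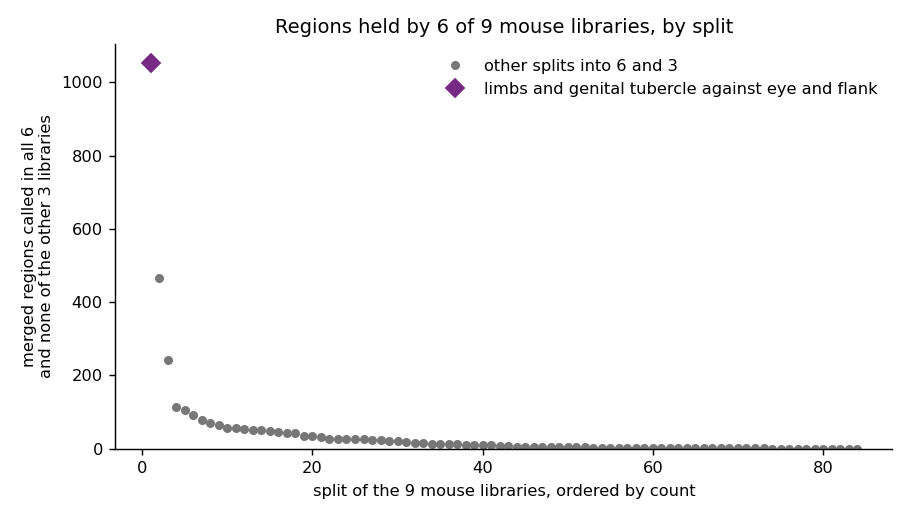
Number of merged regions called in all 6 libraries of a split and in none of the other 3 (vertical axis, regions), for each of the 84 splits of the 9 mouse libraries ordered by that count (horizontal axis, rank; 1 point per split). The split into limbs with genital tubercle against eye with flank (diamond) stood at 1052 and the next at 467.

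Regions called in every library of a tissue and in no other tissue were counted last in the mouse. Genital tubercle alone was called at 4528 regions, eye alone at 2846, both limbs alone at 2062, forelimb alone at 1357 and hindlimb alone at 812. Flank alone was called at 4185, from 1 library. Among the mouse windows named here, which were chosen by count, the eye window from 34 to 35 Mb on chromosome 3 had the highest share of its class. In it 28 of 56 regions (50%) were called in both eye libraries alone. Eye peaks covered 22.6 ± 6.06 kb there, forelimb peaks 0.395 ± 0.170 kb, hindlimb peaks 0.156 ± 0.220 kb and genital tubercle peaks 0.170 ± 0.240 kb (SD, n = 2 each), and flank peaks 0 kb. A window on chromosome 2 from 105000001 to 106000000 and the one from 79 to 80 Mb on chromosome 13 followed with 22 of 56 and 21 of 54 regions.

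The eye region with the highest score lay on chromosome 3 from 17685658 to 17687181 and was covered over 1.40 ± 0.180 kb (SD, n = 2). Genital tubercle windows were again those from 119 to 120 Mb (41 regions) and from 120 to 121 Mb (34 regions) on chromosome 5, then 72 to 73 Mb on chromosome 12 (28 regions). Among regions of the genital tubercle alone, those on chromosome 5 from 119969072 to 119970436 (1.32 ± 0.0651 kb covered) and on chromosome 13 from 31138115 to 31139026 (0.907 ± 0.00707 kb covered; SD, n = 2 each) followed the regions already named. The limbs alone added regions on chromosome 3 from 83412199 to 83414530 and on chromosome 18 from 49376517 to 49377920. Flank regions were densest from 81 to 82 Mb on chromosome 4 (31 of 86). Regions called in all 9 libraries were densest from 23 to 24 Mb on chromosome 13 (31 of 104), from 69 to 70 Mb on chromosome 11 (29 of 136) and from 79 to 80 Mb on chromosome 10 (27 of 122).

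No test was run on these counts, and their order depended on the libraries used. Eye regions numbered 4991 without eye 1 and 11109 without eye 2, and genital tubercle regions 11061 without genital tubercle 1 and 8465 without genital tubercle 2. Regions of both limbs alone numbered 3222 without forelimb 1. Forelimb regions numbered 8278 without forelimb 1, 5920 without forelimb 2 and 2472 without hindlimb 2, and hindlimb regions 7747 without hindlimb 1, 3008 without hindlimb 2 and 2114 without forelimb 2. Beside the 8278 forelimb and the 7747 hindlimb regions, genital tubercle alone stood at 4703 and 4585. Without forelimb 1 and hindlimb 1 together, regions of both limbs alone (6994) outnumbered those of the genital tubercle (4795), and with equal lists those of the eye did (2332 against 2026).

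Lizard limbs and hemiphallus were compared with 1 library per tissue. Both limbs without the hemiphallus accounted for 19732 regions (29.4%), all 3 tissues for 13161 (19.6%) and the hemiphallus alone for 6075 (9.05%). Hindlimb alone accounted for 16849 (25.1%) and forelimb alone for 9601 (14.3%), so each limb had more regions of its own than the hemiphallus. Regions of both limbs without the hemiphallus were led by a pair on lizard chromosome 3, from 8045962 to 8051316 (5.33 kb covered in forelimb, 5.21 kb in hindlimb) and from 8516774 to 8527119 (9.95 kb and 10.3 kb). Their window, from 8 to 9 Mb, held 85 such regions among 169 (50.3%), with 74.4 kb covered in forelimb, 87.1 kb in hindlimb and 0.426 kb in hemiphallus. The next windows were 41 to 42 Mb on chromosome 2 (80 of 173) and 13 to 14 Mb on chromosome 6 (75 of 208).

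The hemiphallus alone was called most often on 1 unplaced scaffold (106 of 138 regions in its first Mb) and, among chromosomes, from 31 to 32 Mb on chromosome 1. There it held 80 of 123 regions (65.0%), and peaks covered 69.8 kb in hemiphallus, 14.0 kb in forelimb and 22.1 kb in hindlimb. That window also contained the named hemiphallus regions from 31723366 to 31727613 and from 31981382 to 31982071. On chromosome 2 a 24.2-kb stretch from 4642808 to 4667004 held the first and the fifth hemiphallus regions, and the region from 164932418 to 164933294 completed the 5. The 5 top forelimb regions without another call all lay in a 25.9-kb stretch of 1 unplaced scaffold (10.17 kb covered in forelimb), and those of hindlimb in a 61.1-kb stretch of another (39.9 kb covered in hindlimb). Among regions called in all 3 tissues, those on chromosome 2 from 156285922 to 156286641 and on chromosome 3 from 141578935 to 141580011 scored highest.

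The lizard limbs shared more with each other than with the hemiphallus, with Jaccard indices of 0.544 between limbs, 0.266 between forelimb and hemiphallus and 0.233 between hindlimb and hemiphallus. Named chromosomes held 59.2% of forelimb, 61.2% of hindlimb and 59.9% of hemiphallus peaks, and unplaced scaffolds the rest. With 1 library per tissue, these differences could not be set against a spread between replicates. The hemiphallus list was the shortest, and with lists of 23906 peaks from each tissue the regions of both limbs without the hemiphallus numbered 6744.

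Set side by side, the limb and genital tissues of both species shared many peaks. In the mouse, 53.1 ± 6.51% of limb peaks overlapped a genital tubercle peak and 51.2 ± 9.17% of genital tubercle peaks overlapped a limb peak (SD, n = 8 ordered pairs each). Of eye peaks 53.6 ± 11.2% (SD, n = 8) and of flank peaks 57.9 ± 8.27% (SD, n = 4) overlapped a limb peak too. In the other direction 41.4 ± 6.2% of limb peaks overlapped an eye peak (SD, n = 8) and 29.3 ± 5.10% a flank peak (SD, n = 4). In the lizard, 69.4% and 71.1% of hemiphallus peaks overlapped a forelimb and a hindlimb peak, and 31.4% of forelimb and 28.1% of hindlimb peaks overlapped a hemiphallus peak. No tissue outside limbs and genitalia was sampled in the lizard, so its shares cannot be called particular to them. Peaks shifted at random along the chromosomes gave 0.958% for mouse limb peaks in genital tubercle and from 1.49 to 3.36% for the lizard pairs of limb and hemiphallus. With lists limited to 23906 top-scoring peaks, the lizard shares became 59.3% of hemiphallus peaks in either limb, 51.5% of forelimb and 50.1% of hindlimb peaks in hemiphallus. Mouse lists of 19621 gave 60.9 ± 1.16% of limb peaks in genital tubercle, 54.1 ± 1.93% in eye (SD, n = 8 ordered pairs each) and 44.7 ± 0.336% in flank (SD, n = 4). In the reverse direction the shares of genital tubercle peaks were 60.6 to 63.5% in forelimb 2 and hindlimb 2, 53.0 to 55.0% in eye and 46.2 to 47.1% in forelimb 1 and hindlimb 1. No test between species was made, since coordinates were not converted between the genomes, stages differed and list sizes moved the lizard limb share by over 1.5 times.

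**Figure D4:**
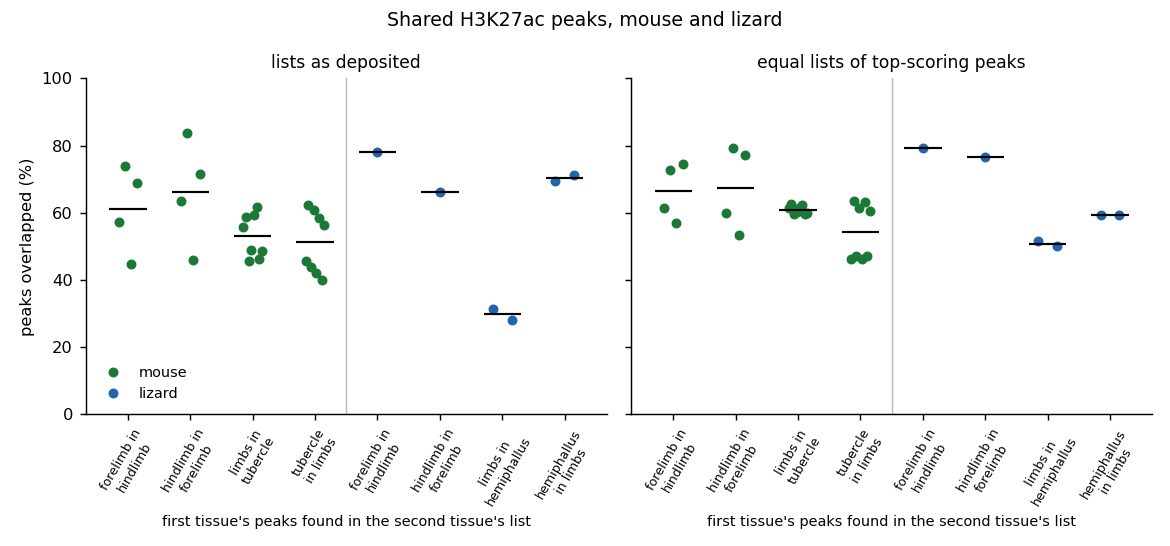
Percent of the peaks of a first tissue overlapped by peaks of a second (vertical axis), in the mouse and the lizard, with lists as deposited (left) and with equal lists of top-scoring peaks (right); each point is 1 ordered pair of libraries and bars are means. The lizard limb shares in hemiphallus stood at 28.1 and 31.4% with lists as deposited and at 50.1 and 51.5% with equal lists.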

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

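Resized peaks, equal lists of resized peaks and leaving out forelimb 1 with hindlimb 1 were chosen only after the data were seen; the other alternatives were not. Of 557 alternative values for 40 results under 19 settings, 332 stayed within the limits. The limits were 1 SD over pairs of libraries, the counting interval or 1.5 times the count. For the permutation test, the exact one-sided p had to stay on the same side of 0.05. The limb index with genital tubercle minus that with eye used the SD of the genital tubercle pairs, and values without a spread had to be unchanged. The exceptions among the 17 results that answer a comparison follow. Counts depend on how many peaks were called, and so on a sequencing depth that is unknown; shares and Jaccard indices depend on it too. Requiring an overlap of 50% of the shorter interval cannot change a count of regions, since a merged region holds its peaks whole, so those values, though among the 332, say nothing about stability. Distal regions and gene lists were not run, because no annotation was used. Classes that need flank had no value without the flank library, and bins, merging and a call in 1 replicate gave no Jaccard index. The labels give library numbers no shared animal, batch or day. Replicate differences of forelimb and hindlimb correlated at 0.152 and those of other pairs of tissues at -0.0211 to 0.0483, so only the limb libraries went together by number, weakly by this measure. With pairs of equal number alone, the Jaccard index was 0.467 between forelimb and hindlimb and 0.306 between limbs and genital tubercle, and the limb index with genital tubercle minus that with eye was 0.0567.

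Leaving out 1 mouse library gave 2286 to 11540 forelimb regions without hindlimb (highest without forelimb 1), 1374 to 10639 hindlimb regions without forelimb (hindlimb 1), 2813 to 4365 limb regions without genital tubercle (forelimb 1) and 5638 to 12809 genital tubercle regions without limb (genital tubercle 1). It gave 1146 to 1609 regions of limbs and genital tubercle without eye or flank (highest without eye 1), 2118 to 3222 limb-only (forelimb 1), 4585 to 11061 genital-tubercle-only (genital tubercle 1) and 2866 to 11109 eye-only regions (eye 2). Fewer libraries required or excluded raise such counts by construction. The within-tissue minus between-tissue Jaccard index was 0.0692 to 0.179, and its exact one-sided p passed 0.05 without eye 1, eye 2, genital tubercle 1 or genital tubercle 2, each of which leaves 1 replicated tissue fewer.

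With a call in 1 replicate per tissue, which asks for less, counts rose to 15930 for forelimb without hindlimb, 12591 for hindlimb without forelimb, 10709 for limb without genital tubercle and 15812 for genital tubercle without limb. Regions in limbs and genital tubercle rose to 18584, those without eye or flank to 3832, eye-only to 12391, genital-tubercle-only to 13721 and limb-only to 8204. Without forelimb 1 and hindlimb 1, which also asks for less, counts were 12761 for forelimb without hindlimb, 11542 for hindlimb without forelimb, 9258 for limb without genital tubercle, 2065 for limbs and genital tubercle without eye or flank and 6994 for limb-only.

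Shorter lists lowered the counts that follow. They hold fewer calls but also exclude fewer regions, so the fall was not fixed in advance. The top-scoring 50% gave 1183 regions for forelimb without hindlimb, 780 for hindlimb without forelimb, 1286 for limb without genital tubercle, 2375 for genital tubercle without limb, 5869 for all limb and genital tubercle libraries and 522 without eye or flank. It gave 3379 in all 9 libraries, 971 limb-only, 1912 genital-tubercle-only and 960 eye-only. In the lizard it gave 7996 in all 3 tissues, 10220 in both limbs without hemiphallus, 2190 hemiphallus-only, and 78.6% of hemiphallus peaks in a limb list. Equal lists gave 1019 for forelimb without hindlimb, 970 for hindlimb without forelimb, 1143 for limb without genital tubercle, 2945 for genital tubercle without limb, 6005 for all limb and genital tubercle libraries and 310 without eye or flank. They gave 746 limb-only, 2026 genital-tubercle-only, 6744 in both lizard limbs without hemiphallus and 59.3% of hemiphallus peaks in a limb list.

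For the settings that follow, the cause was not tested. Bins of 500 bp gave 668 for forelimb without hindlimb, 426 for hindlimb without forelimb, 940 for limb without genital tubercle, 4710 for all limb and genital tubercle libraries and 570 without eye or flank. They gave 2439 in all 9 libraries, 721 limb-only and 3809 lizard hemiphallus-only. Merging within 500 bp gave 1370 for forelimb without hindlimb, 754 for hindlimb without forelimb, 3499 for genital tubercle without limb, 1762 eye-only, 2729 genital-tubercle-only, 1373 limb-only and 3687 hemiphallus-only. An overlap of 50% gave 68.2% of hemiphallus peaks in a limb list.

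Resized peaks gave 1334 for forelimb without hindlimb, 705 for hindlimb without forelimb, 3443 for genital tubercle without limb, 1824 eye-only, 2662 genital-tubercle-only, 1370 limb-only and 3560 hemiphallus-only. They gave 60.5% of genital tubercle peaks and 74.6% of hemiphallus peaks in a limb list. Equal resized lists gave 637 for forelimb without hindlimb, 611 for hindlimb without forelimb, 992 for limb without genital tubercle, 2149 for genital tubercle without limb, 5390 for all limb and genital tubercle libraries and 263 without eye or flank. They gave 1674 eye-only, 1466 genital-tubercle-only, 644 limb-only and 5081 in both lizard limbs without hemiphallus, with 60.5% of genital tubercle and 62.2% of hemiphallus peaks in a limb list.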

Other observations

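The counts over splits of the 9 libraries, the tests with resized peaks, the shares of limb-specific regions in other tissues, the ratios over 6 pairs of limb libraries and the need for a flank replicate in the mesenchyme test were chosen only after the results were seen.

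Regions that set 1 limb apart from the other were looked up in the other tissues. Of the 2283 regions in forelimb and no hindlimb library, 412 (18.0%, 95% exact interval 16.5 to 19.7%) were in both genital tubercle libraries, 6.18% in both eye libraries and 7.27% in flank. The 1372 regions in hindlimb and no forelimb library gave 241 (17.6%, 15.6 to 19.7%), 7.65% and 8.97%. All 90434 regions gave 25.9%, 17.8% and 17.9% in the same order, and all 47939 regions of equal lists 28.8%, 26.4% and 34.2%, but these hold the regions common to all limb libraries, so they set no base for limb-specific ones. With equal lists the forelimb shares were 24.0% (21.4 to 26.8%) in genital tubercle, 15.1% (12.97 to 17.5%) in eye and 17.0% (14.7 to 19.4%) in flank. The hindlimb shares were 19.5% (17.0 to 22.1%), 14.5% (12.4 to 16.9%) and 16.6% (14.3 to 19.1%), so the hindlimb intervals for genital tubercle and flank overlapped. Genital tubercle and eye shares need calls in 2 libraries, however, and flank shares in 1. Single genital tubercle libraries held 30.1 to 32.6% of the forelimb and 24.6 to 25.9% of the hindlimb regions with equal lists. Single eye libraries held 21.8 to 22.1% and 20.1 to 21.6%. Among the 100 forelimb regions with the highest score in their weaker library, 33 were in both genital tubercle libraries, 11 in both eye libraries and 10 in flank. The 100 hindlimb regions chosen likewise gave 29, 11 and 13. The forelimb share fell to 10.1% without forelimb 1 and 9.19% without forelimb 2 and rose to 27.2% without genital tubercle 1 and 32.2% without hindlimb 2. The hindlimb share fell to 8.67% without hindlimb 1 and 8.66% without hindlimb 2 and rose to 30.8% without forelimb 2.

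Genital tubercle also shared regions with flank. A total of 451 regions were called in genital tubercle and flank and in no limb or eye library (680 without genital tubercle 1). A region on chromosome 5 from 119586560 to 119589890 led them, and its window from 119 to 120 Mb held 10. With equal lists, genital tubercle with flank alone gave 414 regions. Limbs with genital tubercle alone, which need calls in more libraries, gave 310. Genital tubercle with eye alone gave 120, limbs with flank alone 82 and limbs with eye alone 118. The regions shared by limbs and genital tubercle alone lay near each other: 45.8% had another within 50 kb, above each of 1000 random draws of as many regions from all regions (median 11.4%, highest 16.4%) and from the 3299 regions called in 6 libraries (median 16.8%, highest 21.3%). Peaks that lie apart form separate regions, so a long marked stretch can hold several regions of the same class, while both pools mix classes. The draws therefore cannot show that nearness is particular to the shared regions, and no other class was drawn.

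The limb libraries parted more by number than by limb, with 6507 against 3655 regions, a ratio of 1.78. Short peaks in forelimb 1 and hindlimb 1, fewer called peaks, or both together could produce this. The ratio stayed above 1 with resized peaks (1.56), equal lists (1.46) and equal lists of resized peaks (1.46), though each lowered it. With equal lists, 2496 regions were in both libraries numbered 2 alone and 406 in both numbered 1 alone. Equal resized lists gave 1546 and 280. Equal lists match the number of peaks and not of sites, and resizing restores no missed call. These ratios therefore cannot decide whether short or fewer peaks were the whole cause. A difference in how the libraries numbered 1 and 2 were prepared or sequenced stays open, since the labels give no batch, and no biological explanation was tested.

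The 1052 regions of limbs and genital tubercle without eye or flank could reflect chance, the smaller eye 2 and flank lists, or mesenchyme common to limbs, genital tubercle and flank. Of the 84 splits of single libraries, 1, the real one, gave as many, and the next gave 467. Most splits part replicates, which lowers their counts, so this rank cannot exclude chance. Only 4 keep tissues whole (1 of 4 gave as many, the highest other 241), too few for a share under 0.05. With equal lists the count was 1.197 times the next highest (310 against 259, 95% counting bounds of the ratio 1.01 to 1.41). With equal lists of resized peaks it was 1.71 times (263 against 154). No other split gave as many in either setting. However, the bounds take regions as independent, though many lay near each other. Both times the next highest split left out forelimb 1, hindlimb 1 and flank. Those limb libraries had short peaks, but whether this raised the count of that split was not tested. How far these ratios weigh against list size as the whole cause therefore cannot be judged. These regions lack a flank call by definition, so shared mesenchyme needs calls missed in flank, and flank minus the higher eye share of the regions in all 6 libraries was -8.33 percentage points (79.1% in flank, 87.4% and 85.6% in the eye libraries), which met the bound set beforehand against it, but calls missed in the only flank library would lower that share too, so it cannot be told apart. A property of outgrowing buds, and the earlier stage of the eye, stay open and were not tested.

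Genital tubercle regions without a limb call outnumbered limb regions without a genital tubercle call by 2.00 times. This could follow from requiring 4 limb libraries against 2 of genital tubercle, or from the short peaks of forelimb 1 and hindlimb 1. With resized peaks the ratio stayed at 1.75 (3443 against 1964), so peak length alone did not account for it with 4 limb libraries required. With only forelimb 2 and hindlimb 2, whose peaks were not short, resized peaks gave 0.708 (3741 against 5287). Resizing restores no missed call, so the libraries with short peaks are not set aside as a cause. With 2 libraries against 2 the mean ratio was 1.18 (1.09 for forelimb, 1.27 for hindlimb), and 5 of 6 pairs of limb libraries stayed above 1, up to 2.42, but forelimb 2 with hindlimb 2, which the bound set for this test left out, gave 0.656. With equal lists 6 of 6 pairs stayed above 1, up to 2.50, and that pair gave 1.04 (95% counting bounds 0.989 to 1.09), or 1.07 (1.01 to 1.13) with equal lists of resized peaks, so the number required cannot be told apart from a true difference while this pair lies on both sides of 1 by setting, and the later stage of the genital tubercle was not tested.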
